A study of Fusarium verticillioides with 4 samples.

How the data were processed

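The series holds 4 single-colour NimbleGen expression arrays of Fusarium verticillioides strain M3125, a wild-type maize pathogen. Per the labels, cultures grew for 3 days at 27 °C and 250 rpm in 3 mL of potato dextrose broth buffered with 0.1 M sodium phosphate. DETA NONOate, a compound that releases nitric oxide (NO) in solution, was then added at 1.5 mM to 2 cultures, and 2 control cultures were mock-treated. All were harvested after 30 min. Total RNA of each culture was labelled with Cy3 and hybridised to 1 array, so the replicate is the culture and n = 2 per group. The labels describe the cultures as separate. Each culture had an array of its own, so effects of single arrays cannot be separated from those of single cultures, and their number limits the precision of every value.

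Each feature is represented by 2 probe blocks, with 6 probe pairs per block for 14148 of the 14163 F. verticillioides transcripts and at least 1 for the others. For every array the authors deposited a table of un-normalized mean probe intensity, and another of linear intensity that, per the file headers, had been processed by RMA (robust multi-array average: background correction, quantile normalization between arrays and a median-polish summary of probes). The software, its version and the gene models behind the probes are not given in the sources used here. The RMA values span all 31917 features of the array, of which 14163 are F. verticillioides transcripts. The others are named for Aspergillus flavus, F. graminearum or maize, or carry IDs with no organism. The series' value table of 28326 entries is identical to the RMA intensity (largest difference 0). The coefficient of variation of the probes, also deposited by the authors, was used for random control probes alone.

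Starting from these files, RMA intensities were put on the log2 scale and averaged over both probe blocks, giving 1 value per transcript and array. The SD of the difference between blocks lay between 0.11 and 0.14 log2 units. Detection was set against random control probes. A transcript was called detected on an array when its un-normalized signal exceeded the mean of the random probes plus 2 SD, a threshold of 196 and 128 on the control arrays and 200 and 226 on the NO-exposed arrays. Above or below background means above or below this threshold. It is set on un-normalized signals and does not order RMA values, so a value below it can exceed that of a detected feature. The 11095 transcripts detected on at least 2 of the 4 arrays were tested, and 3068 were not. The largest un-normalized signal was 56422. It is a mean over probes, so whether single probes were saturated is unknown.

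Groups were compared with limma 3.58.1 (R 4.3.3), using lmFit and eBayes on log2 values, as NO-exposed minus control without covariates, in a two-sided test. P-values were adjusted by the Benjamini-Hochberg method over the 11095 transcripts, with a threshold of 0.05. The fit had 2 residual and 5.85 prior degrees of freedom. Gene lists with at least 5 tested members were compared with all other tested transcripts by limma's camera at a preset inter-gene correlation of 0.01, adjusted over 31 lists. Values with an estimated correlation and limma's fry, which tests whether members move on balance 1 way, were computed beside it. With an estimated correlation camera relies on the 2 residual degrees of freedom alone. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9 served for the other steps.

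Transcript IDs (FVET numbers) and product names are those of the array. Of the 14163 transcripts 3080 had an informative product name, 2793 of them tested, and most names were given by the array's designers as similarity to a known protein. The numbers do not correspond to the FVEG locus tags of the reference table: over 13002 shared numbers the correlation of log2 lengths was 0.0147. No chromosome position is therefore given. Of 43 gene lists fixed beforehand, 37 were matched by product name, and 6 defined by FVEG locus range (the fumonisin, bikaverin, fusarin, fusaric acid, FDB1 and FDB2 loci) could not be used.

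The comparison, the test, the detection rule, the gene lists, the rule for naming genes and most alternative settings were chosen before the data were examined. The rule named, among transcripts past the threshold whose NO-exposed values both lay on 1 side of both control values, the 12 with the largest rise and the 12 with the largest fall that had an informative product name, and the 3 largest in each direction whatever the name. It added every tested member of the lists for NO detoxification, nitrate and nitrite assimilation, and alternative oxidase, and up to 4 members of smallest p of each other list described with examples. It gave 101 transcripts. The 18 lists described with examples were picked after the list results had been seen, and all others are given as counts. Transcripts outside the rule are named as such. Where a transcript was below the detection threshold on both arrays of 1 group, the fold is written "nominally". It is the ratio of group means of RMA values, with the dim group below that threshold, and is no bound. Setting the dim values no lower than the lowest among detected transcripts (3.65 to 3.91 on the log2 scale per array) left these folds unchanged.

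The fit was tested on simulated data with the real means and 200 transcripts changed by known folds. Of the 11095 transcripts, limma called 16% of those changed 1.5-fold, 90% of those changed 2-fold and 100% of those changed 3-fold or 4-fold, all in the right direction, with 7 false calls. In the same simulation camera called the 1 list of 20 transcripts that was shifted by 0.5 log2 units, out of 11 lists, and 0 of the unshifted ones. Far more transcripts changed in the data (1680 higher and 3365 lower), so these call rates need not hold there. Simulated transcripts were also independent, whereas estimated correlations were 0.34 and 0.51 for cytosolic and mitochondrial ribosomal proteins. The list result therefore does not cover lists of correlated members.

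Alternatives set beforehand were un-normalized signals after normexp background correction (offset 50) with quantile normalization or with median scaling, the series' value table, no detection filter, an intensity trend or a robust prior in eBayes, the replicate number as a block, a 2-fold minimum, and each array left out in turn. Chosen after seeing the data were the RMA values centred on the median of the tested transcripts, quantile normalization over the tested transcripts, un-normalized signals with quantile normalization and no background correction, detection on all 4 arrays (10289 transcripts), each probe block alone, the crossed pairing of replicate numbers, and a pair of changes to list membership. Averaging in place of median polish was not run, since the values used here are already summarised per block.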

Results

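Transcript levels of Fusarium verticillioides were measured on 4 arrays, 2 of mock-treated control cultures and 2 of cultures exposed for 30 min to the NO donor DETA NONOate. Between 73.3% and 82.1% of the 14163 F. verticillioides transcripts were detected on each array, against 2.6% to 3.7% of the features named for Aspergillus flavus, a fungus absent from the labels. Median un-normalized signal of the F. verticillioides transcripts was 2418.5 and 2762.5 on the control arrays and 1837.5 and 1888 on the NO-exposed arrays, where random probes averaged 105 and 83, and 108 and 113. Across tested transcripts, log2 values correlated at 0.994 and 0.995 within the control and the NO-exposed group and at 0.940 to 0.949 between groups. These correlations are across transcripts, which are not independent replicates. The 1 comparison of the design, NO-exposed against control, asks which transcripts respond to the NO donor. No group received donor that had already released its NO. Effects of NO therefore cannot be told apart from other effects of DETA NONOate.

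Transcripts of enzymes that remove NO rose after exposure. Cytochrome P450 55A1 (FVET_10790), named like the fungal NO reductase that turns NO into nitrous oxide, rose 21.1-fold, from 9.72 ± 0.38 to 14.12 ± 0.10 on the log2 scale (mean ± SD, n = 2 per group; adjusted p = 4.9e-06). Flavohemoglobin FVET_13847, of a family that oxidises NO to nitrate, rose 16.7-fold, from 9.90 ± 0.44 to 13.97 ± 0.03. A second flavohemoglobin, FVET_11203, was already abundant in control cultures at 14.25 ± 0.31 and rose 2.55-fold to 15.60 ± 0.03. These 3 make up the list of NO detoxification transcripts, and all passed the test. The largest rise of any tested transcript was that of FVET_08691, named major anaerobically induced outer membrane protein, a name shared with a copper-containing nitrite reductase of Neisseria. It was above background on 1 of 2 control arrays, at 6.46 ± 0.05, and reached 14.41 ± 0.04 after exposure, a fitted change of 246-fold (adjusted p = 7.53e-08).

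Of 8 transcripts in the list for nitrate and nitrite assimilation, 4 rose and 1 fell (4 and 2 adjusted over the list alone). Nitrate reductase FVET_07308, which reduces nitrate to nitrite, rose 3.03-fold from 13.67 ± 0.37 to 15.27 ± 0.05. Nitrate reductases FVET_01629 and FVET_12108 rose 1.75-fold and 1.57-fold. Nitrite reductase FVET_02071, the next enzyme of the path, rose 1.56-fold from 14.98 ± 0.18 to 15.62 ± 0.05, and its call ended without control replicate 2 (change 0.51 on the log2 scale). The 4 transcripts for the molybdenum cofactor that nitrate reductase needs did not share this rise. FVET_14061 fell by 0.39 on the log2 scale (adjusted p = 0.0347) but stood at 0.01 under median scaling, and its call ended whichever array was left out, at changes of -0.38 to -0.40. Transcripts FVET_04223, FVET_14062 and FVET_01393 differed by -0.37, -0.23 and 0.00 and did not pass, although FVET_04223 passed with an intensity trend and among transcripts detected on all 4 arrays. As a list these 8 did not stand apart from other transcripts (camera adjusted p = 0.195). Alternative oxidase FVET_01479, a terminal oxidase less sensitive to NO than cytochrome c oxidase, differed by 0.17 ± 0.13 (SE; adjusted p = 0.317). Alternative NADH dehydrogenase FVET_10333 differed by 0.31 ± 0.16 (SE; adjusted p = 0.14). Both passed under median scaling, at 0.57 and 0.63, and FVET_10333 also with an intensity trend.

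**Figure D1:**
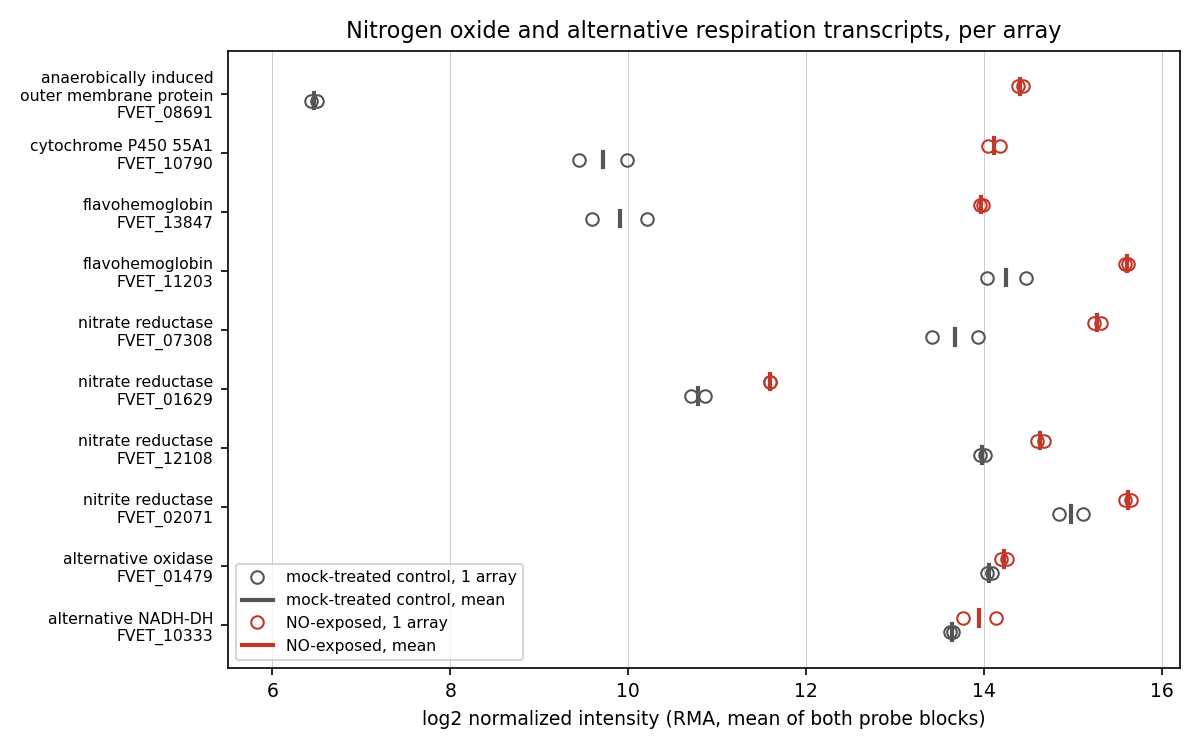
Log2 normalized intensity (horizontal axis) of 10 transcripts (vertical axis) on each of the 4 arrays; circles are single arrays and bars are group means, grey for mock-treated control and red for NO-exposed. P450 55A1 and flavohemoglobin FVET_13847 moved from 9.72 and 9.90 to 14.12 and 13.97, whereas alternative oxidase stayed between 14.06 and 14.23 in its group means.

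Among the other named transcripts with the largest rises, GABA permease FVET_00007, of a family that imports gamma-aminobutyrate, rose 66.7-fold from 8.70 ± 0.14 to 14.76 ± 0.05. Amino acid permease FVET_01602 rose 15.0-fold. Copper amine oxidases, which turn primary amines into aldehydes, rose 11.2-fold (FVET_13769) and 10.3-fold (FVET_11989, named as peroxisomal), while another, FVET_04399, fell 4.88-fold. Aldehyde dehydrogenase 9 (FVET_11991) rose 19.1-fold, from 10.73 ± 0.04 to 14.98 ± 0.09. Transcriptional regulators FVET_01724 and FVET_10418 rose 23.4-fold and 21.4-fold, P450 monooxygenase FVET_03333 15.7-fold, and 3-ketoacyl-CoA thiolase FVET_03319, an enzyme of fatty acid oxidation, 13.7-fold. FVET_10511, a conserved protein of no stated function, rose from 6.69 ± 0.29, above background on 1 of 2 control arrays, to 13.99 ± 0.07.

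Among the named transcripts with the largest falls, proline permease FVET_11784 fell 6.53-fold, from 12.97 ± 0.04 to 10.26 ± 0.16, and delta-1-pyrroline-5-carboxylate dehydrogenase FVET_03751, the last enzyme of proline breakdown, fell 6.41-fold. MSF transporter FVET_10105 fell 14.7-fold, LAP1 (FVET_06713) 8.59-fold, the DUF895 membrane protein FVET_12124 5.44-fold, 3-oxoacyl-acyl-carrier-protein reductase FVET_02751 5.01-fold and monosaccharide transporter FVET_12706 4.94-fold. Another 5 transcripts were below background on both NO-exposed arrays, so their folds are nominal ratios of group means and no bounds. Phenylacetate hydroxylase P450 FVET_04422 was nominally 7.26-fold lower and beta-fructofuranosidase FVET_11950, which splits sucrose, 7.12-fold. Extracellular elastinolytic metalloproteinase FVET_13650 was nominally 6.27-fold and metalloprotease 1 (FVET_13452) 5.38-fold lower. The unnamed protein FVET_00224 was nominally 17.2-fold lower, and FVET_00232, also unnamed, fell 18.4-fold.

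In all, 1680 transcripts were higher and 3365 lower after exposure in limma's test of 11095 transcripts, of which 563 and 1068 changed at least 2-fold. Thus 33.3% of the changed transcripts were higher. This share depended on the scaling. It was 51.1% under median scaling of un-normalized signals (2803 higher, 2683 lower), 48.1% under quantile normalization over the tested transcripts and 42.0% after centring on them, but 36.3% under quantile normalization of un-normalized signals, with normexp or without background correction. With a 2-fold minimum, 655 were higher and 678 lower under median scaling, and 728 higher and 652 lower under quantile normalization over the tested transcripts. The median change of all tested transcripts was -0.15 on the log2 scale, so a list with a median near that value moved like the tested transcripts as a whole. Under median scaling it was 0.02, and medians of lists of unlike function shifted up by more. The respiratory chain went from 0.12 to 0.53, chaperones from 0.05 to 0.50 and mitochondrial ATP synthase from -0.03 to 0.38. Iron-sulfur cluster assembly did not, going from 0.36 to 0.33. Counts of rises under median scaling are therefore not particular to single lists. The SD of differences between replicates was 0.243 in the control and 0.245 in the NO-exposed group.

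**Figure D2:**
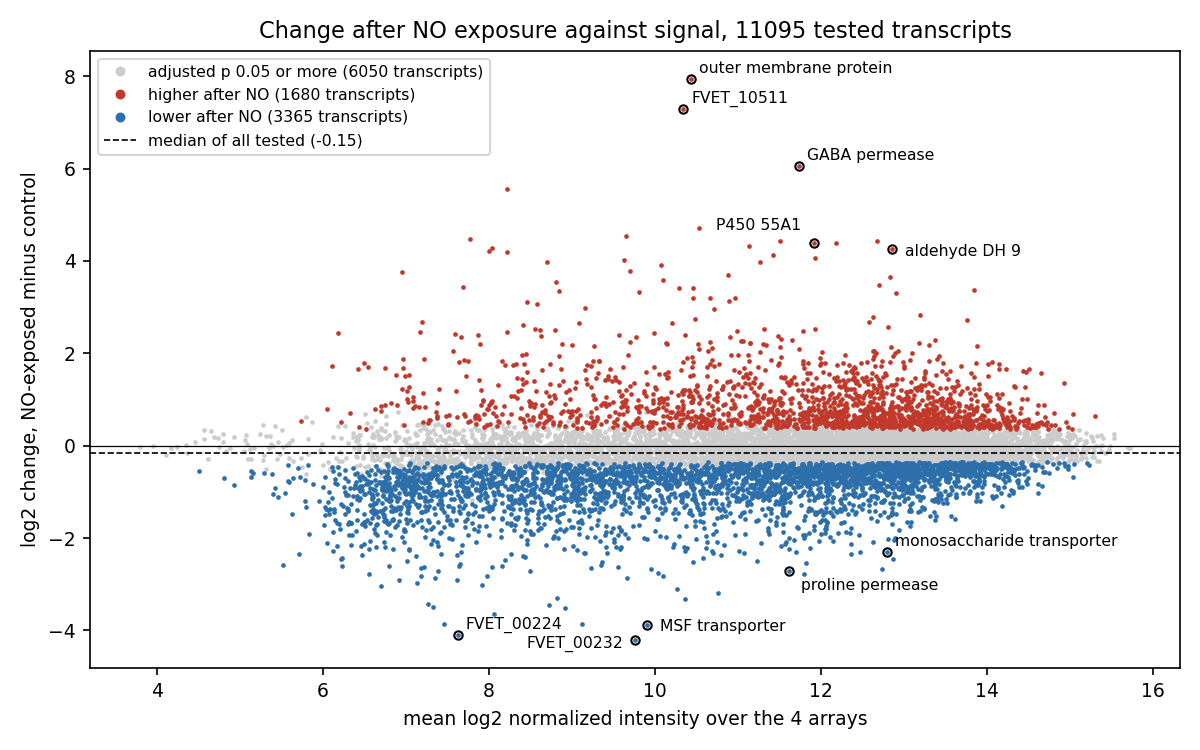
Log2 change, NO-exposed minus control (vertical axis), against mean log2 normalized intensity over the 4 arrays (horizontal axis), with 1 point per tested transcript. Red points are the 1680 higher and blue points the 3365 lower transcripts, grey points had an adjusted p of 0.05 or more, circled points are named, and the dashed line is the median of -0.15; under median scaling 2803 were higher and 2683 lower.

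Transcripts for making ribosomes rose together. Of 23 ribosome biogenesis transcripts 21 rose, 19 of them at least 2-fold, and 0 fell, with the same 21 adjusted over the list alone. RPF2 (FVET_01304), an assembly factor of the large subunit, rose 5.21-fold from 10.30 ± 0.17 to 12.68 ± 0.01, RLP24 (FVET_05390) 4.70-fold, Bms1 (FVET_06415) 4.40-fold and FVET_08913 4.04-fold. Their median change was 1.21 on the log2 scale (camera adjusted p = 3.02e-15; adjusted p = 0.697 with an estimated correlation). Of 11 mitochondrial ribosomal protein transcripts 10 rose, by less: L14 (FVET_05623) 1.94-fold, S19 (FVET_09737) 1.88-fold, L19 (FVET_06179) 1.78-fold and YmL8 (FVET_02700) 1.58-fold (camera adjusted p = 2.02e-05; adjusted p = 0.894 with an estimated correlation). Of 54 cytosolic ribosomal protein transcripts 19 rose (16 adjusted over the list alone) and 0 fell. Under median scaling, which also raised the medians of lists of other functions, all 54 rose. Their median change was 0.31, with 60S acidic protein FVET_05409 at 2.73-fold, S19 (FVET_09124) at 1.47-fold and L27a (FVET_07198) at 1.45-fold (camera adjusted p = 8.62e-10; adjusted p = 0.894 with an estimated correlation). This list also holds mitochondrial members such as FVET_06179, matched by name. Of 26 tRNA synthetases 5 rose and 0 fell (2 adjusted over the list alone), and 20 rose under median scaling. Those that rose included tyrosyl FVET_00441 (1.92-fold), alanyl FVET_13659 (1.56-fold), lysyl FVET_00633 (1.45-fold) and arginyl FVET_05571 (1.34-fold). Their camera adjusted p was 0.0232 (adjusted p = 0.697 with an estimated correlation), and the call ended without control replicate 2 (0.0621). The calls of FVET_09124, FVET_07198, FVET_13659, FVET_00633 and FVET_05571 each ended without at least 1 of the arrays, at changes of 0.39 to 0.62 on the log2 scale.

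Of 31 lists tested, camera called 8 higher and 0 lower, but with an estimated correlation it called 0 in either direction. That setting relies on the 2 residual degrees of freedom, so a lost call does not show that correlation among members undid it. Estimated correlations were -0.042 for heme synthesis, -0.028 for tRNA synthetases and -0.040 for sulfur assimilation, below the preset 0.01, yet these calls ended too. The list with 21 of 23 members higher was among those that no longer passed. Fry, which asks only whether members move on balance in 1 direction, gave an adjusted p of 0.0267 for ribosome biogenesis and for tRNA synthetases. Of the 2793 tested transcripts with an informative name 545 rose and 736 fell, against 1680 and 3365 of all 11095. Lists were matched by product name, so the main test sets them against mostly unnamed transcripts, of which a larger share fell. Compared with named transcripts alone, a background chosen after seeing the data, 3 lists passed. The calls ended for heme synthesis (camera adjusted p = 0.0794), for the respiratory chain (0.137), and for tRNA synthetases, the tricarboxylic acid and glyoxylate cycles and sulfur assimilation (0.0951 each).

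Heme synthesis transcripts were among the 8 lists. Of 6, 3 rose and 0 fell (the same adjusted over the list alone): delta-aminolevulinic acid dehydratase FVET_02697 by 2.03-fold, 5-aminolevulinate synthase FVET_05321, the first enzyme of the path, by 1.77-fold and coproporphyrinogen III oxidase FVET_11417 by 1.75-fold. Ferrochelatase FVET_04239, which inserts the iron, differed by 0.28 ± 0.13 (SE; adjusted p = 0.112) and passed after centring, under median scaling and with an intensity trend. Under median scaling 5 of the 6 rose. The list had a camera adjusted p of 0.0237 (adjusted p = 0.697 with an estimated correlation), and the call ended without NO-exposed replicate 1 (0.0634). In the sulfur assimilation and methionine list 7 of 24 rose and 3 fell (6 and 2 adjusted over the list alone), with 13 and 3 under median scaling and 11 and 2 under quantile normalization over the tested transcripts. Cystathionine gamma-synthase FVET_05100 rose 2.67-fold, cystathionine beta-lyase FVET_01639 2.40-fold and homocysteine S-methyltransferase FVET_03899 2.23-fold, all steps toward methionine. Alternative sulfate transporter FVET_12099 was below background on both NO-exposed arrays, nominally 2.91-fold lower. This list had a camera adjusted p of 0.0232 (adjusted p = 0.697 with an estimated correlation).

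Of 29 transcripts matched to the tricarboxylic acid and glyoxylate cycles 11 rose and 6 fell (12 and 6 adjusted over the list alone; camera adjusted p = 0.0232; adjusted p = 0.697 with an estimated correlation), with 20 and 4 under median scaling. Several that rose belong by name to amino acid synthesis: 3-isopropylmalate dehydrogenase FVET_03345 (3.34-fold), of leucine synthesis, and homocitrate synthase FVET_08501 (3.28-fold), of lysine synthesis. Malate dehydrogenase FVET_00375 fell 2.74-fold and 2-methylcitrate synthase FVET_00189, of propionate breakdown, fell 2.54-fold. Without 11 members named for another function, a selection made after seeing the data, the remaining 18 were not called (camera adjusted p = 0.532). Of 22 respiratory chain transcripts 2 rose and 1 fell (the same adjusted over the list alone), whereas 19 rose under median scaling. Cytochrome oxidase assembly protein ctaG (FVET_11537) rose 1.88-fold, cytochrome c1 heme lyase FVET_03165 rose 1.67-fold, mitochondrial NADH dehydrogenase FVET_09106 fell 1.75-fold, and subunit B17.2 (FVET_06669) differed by 0.30 (adjusted p = 0.196). The list had a camera adjusted p of 0.0386 (adjusted p = 0.955 with an estimated correlation), and the call ended without control replicate 1 (0.152) and without NO-exposed replicate 1 (0.216). It also ended under quantile normalization of un-normalized signals, with normexp (0.0723) and without background correction (0.0728). Of 15 glycolysis transcripts 1 rose and 5 fell (1 and 6 adjusted over the list alone), but 4 rose and 2 fell under median scaling. Glucokinase FVET_01891 fell 2.53-fold and hexokinase FVET_10649 1.57-fold, phosphoglycerate mutase family protein FVET_02531 fell 1.46-fold (not passing under median scaling), and D-3-phosphoglycerate dehydrogenase FVET_07801, an enzyme of serine synthesis, rose 1.84-fold. The calls of FVET_10649 and FVET_02531 ended without NO-exposed replicate 2, at -0.47 and -0.42 on the log2 scale, and that of FVET_02531 also without control replicate 2 (-0.47).

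Transporter transcripts changed in both directions. Of 36 amino acid permeases 13 rose, 9 of them at least 2-fold, and 12 fell, 4 of them at least 2-fold, with the same counts adjusted over the list alone and 13 and 8 under median scaling. As a list they had a camera adjusted p of 0.217, which was 0.0441 without NO-exposed replicate 1. N amino acid permease FVET_09453 rose 10.2-fold, beside the permeases given earlier. Of 33 sugar transporters 5 rose and 16 fell (6 and 16 adjusted over the list alone), 12 of the latter at least 2-fold. MFS sugar transporters FVET_10994 and FVET_03197 fell 3.74-fold and 3.04-fold, and glucose transporter FVET_11618 was nominally 3.25-fold lower. As a list they had a camera adjusted p of 0.144, which was 0.0369 without control replicate 2 and 0.0263 without NO-exposed replicate 2. Of 29 transcripts named as MFS transporters, a large family of membrane carriers that shares members with the sugar transporters, 3 rose and 15 fell (the same adjusted over the list alone; camera adjusted p = 0.217), with 6 and 10 under median scaling. MFS phosphate transporter FVET_01442 rose 3.08-fold and MFS quinate transporter FVET_11903 was nominally 3.14-fold lower.

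Lists for redox and iron metabolism split. In glutathione metabolism 2 of 10 rose and 3 fell (the same adjusted over the list alone), but 2 rose and 1 fell under median scaling. S-(hydroxymethyl)glutathione dehydrogenase FVET_02934, of a family that also reduces S-nitrosoglutathione, rose 3.15-fold from 13.32 ± 0.05 to 14.97 ± 0.04. Outside the naming rule, FVET_09321, named glutathione-dependent formaldehyde dehydrogenase, differed by -0.58 on the log2 scale (adjusted p = 0.055). Glutathione S-transferase FVET_03834 rose 1.96-fold, while glutathione S-transferase FVET_07467 and lactoylglutathione lyase FVET_04035 fell 1.44-fold and 1.43-fold. Both calls ended under median scaling (-0.27 and -0.31 on the log2 scale), without control replicate 2 (-0.47 and -0.45) and without NO-exposed replicate 2 (-0.34 and -0.38), and that of FVET_07467 after centring (-0.45). In the iron-sulfur list 2 of 5 rose and 2 fell (3 and 2 adjusted over the list alone), with 3 and 1 under median scaling. Assembly proteins FVET_09267 and FVET_11580 rose 2.42-fold and 1.58-fold, and the 2 that fell, FVET_09988 (4.87-fold) and FVET_10797 (1.62-fold, not passing under median scaling), are named as cluster-binding. Of 13 siderophore and iron uptake transcripts 3 rose and 3 fell (the same adjusted over the list alone), and 6 rose and 3 fell under median scaling, with mirB (FVET_12193) 1.92-fold and ferroxidase FVET_07612 1.41-fold higher, and siderochrome-iron transporter FVET_12037 and mirA (FVET_13184) 2.26-fold and 1.66-fold lower. Of 22 aldehyde dehydrogenases 6 rose and 10 fell (7 and 11 adjusted over the list alone), but 9 rose and 8 fell under median scaling. Beside FVET_11991, FVET_00151 rose 2.96-fold, FVET_07258 fell 2.40-fold and FVET_09427 was nominally 3.36-fold lower. All 3 nitronate-oxidising enzymes named 2-nitropropane dioxygenase fell, FVET_04521 by 1.88-fold, FVET_06325 by 1.83-fold and FVET_02106 by 1.35-fold (-0.43 on the log2 scale). The last did not pass under any of 5 other scalings, at -0.18 under median scaling and -0.35 to -0.39 under the others, or without control replicate 1 (-0.44), control replicate 2 (-0.43) or NO-exposed replicate 2 (-0.29). Of 55 proteasome and ubiquitin transcripts 1 rose and 13 fell (0 and 8 adjusted over the list alone), but 6 rose and 4 fell under median scaling. Ubiquitin hydrolase FVET_09272, Pre4 (FVET_01329), Doa1/Ufd3 (FVET_13142) and proteasome activator FVET_06491 fell between 1.49-fold and 1.61-fold. The call of FVET_06491 ended under median scaling and without control replicate 2 (-0.52 on the log2 scale), and those of FVET_13142 and mirB without NO-exposed replicate 2 (-0.52 and 0.82). Ferroxidase FVET_07612 did not pass without control replicate 1 (0.42) or NO-exposed replicate 2 (0.46).

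The remaining lists are given as counts that rose and fell, with those adjusted over the list alone in brackets, and none was called by camera in the deposited values. Among heat shock proteins and chaperones 6 of 21 rose and 4 fell (7 and 5). Under median scaling 14 rose and 1 fell, and camera called this list higher (adjusted p = 0.00717), which made 9 lists. Among thioredoxins, glutaredoxins and peroxiredoxins it was 4 and 4 of 14 (4 and 4; 7 and 2 under median scaling), among catalases, peroxidases and superoxide dismutases 2 and 5 of 13 (2 and 5; 2 and 3 under median scaling), and among old yellow enzymes, quinone and aldo-keto reductases 2 and 11 of 41 (2 and 10), with 14 and 8 under median scaling. In ammonium and glutamine metabolism 1 of 17 rose and 4 fell (1 and 3), with 8 and 2 under median scaling. Among mitochondrial ATP synthase transcripts 0 of 14 rose and 2 fell (0 and 2), with 7 and 1 under median scaling. ABC transporters had 5 and 5 of 16 (7 and 5; 6 and 2 under median scaling), cytochrome P450s 2 and 7 of 16 (2 and 8; 5 and 6 under median scaling), ergosterol synthesis 2 and 3 of 16 (2 and 1; 6 and 1 under median scaling) and DNA repair 1 and 3 of 18 (0 and 1; 3 and 1 under median scaling). Plant cell wall degrading enzymes had 3 and 10 of 27 (3 and 10), but 6 and 5 under median scaling and 7 and 5 under quantile normalization over the tested transcripts. C6 and bZIP transcription factors had 0 and 7 of 21 (0 and 7), but 6 and 5 under median scaling. Of 5 metal ion transport transcripts 0 passed (0), and 1 rose under median scaling. Lists too small for camera were polyketide and nonribosomal peptide synthases, with 0 and 1 of 4 (0 and 1), conidia and development, with 1 and 0 of 4 (1 and 0), and histones, with 0 and 1 of 3 (0 and 1).

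**Figure D3:**
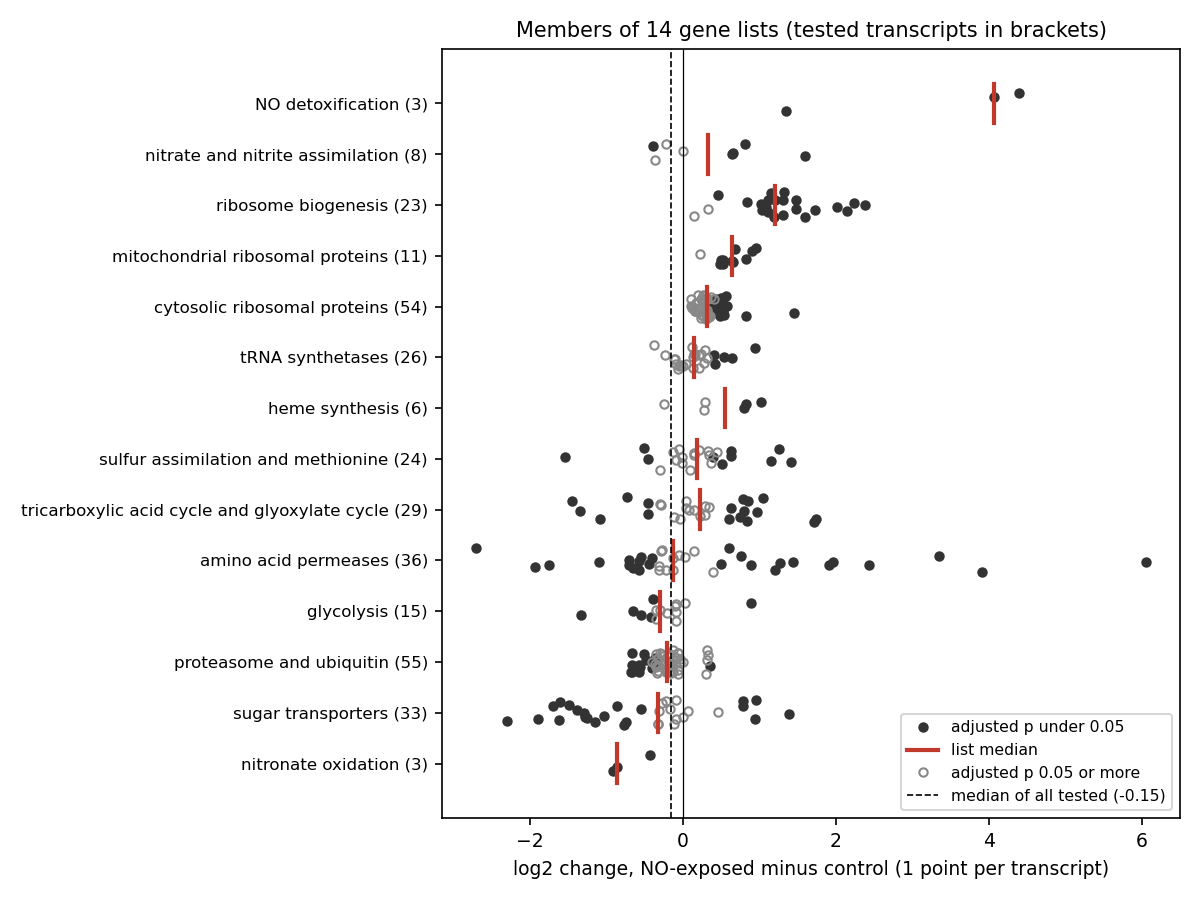
Log2 change, NO-exposed minus control (horizontal axis), of the tested members of 14 gene lists (vertical axis, number tested in brackets), with 1 point per transcript, filled where the adjusted p was under 0.05, and a red bar at each list's median. Ribosome biogenesis members centre on 1.21 and cytosolic ribosomal proteins on 0.31, to the right of the dashed median of all tested transcripts at -0.15; the medians of glycolysis, proteasome and amino acid permeases lie on the other side of 0 under median scaling.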

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

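Of the tests in this part, the one on dim transcripts over 5 scalings was set before its values were seen, and all others were chosen after the result they bear on had been seen. Among its scalings, centring, quantile normalization over the tested transcripts and quantile normalization without background correction had themselves been chosen after seeing the data.

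Signal changed in features outside the F. verticillioides transcripts, which the comparison did not use. These are deposited values, and other scalings were not run for them. After NO exposure 74 of 423 detected features named for A. flavus were higher and 0 lower, with a median change of 0.27 on the log2 scale. Their median level was only 4.85 on that scale, near background. Un-normalized random probes averaged 108 and 113 on the NO-exposed arrays and 105 and 83 on the control arrays. Of 423 detected features named for F. graminearum 151 were higher and 8 lower (median 0.37). Of 1320 detected features whose IDs start with Gf and name no organism, 491 were higher and 76 lower, with a median change of 0.29 against -0.14 for F. verticillioides transcripts of the closest signal. Between 96.2% and 97.6% of all Gf features were detected on each array, against 73.3% to 82.1% of the F. verticillioides transcripts. They may therefore measure RNA of this fungus too, and among them rises outnumbered falls. Of 664 other detected features 122 were higher and 192 lower (median -0.13).

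More transcripts fell than rose, and dim ones most: the share of changed transcripts that rose went from 12.9% in the dimmest eighth to 47.9% in the brightest. Transcript length stays open: the median change of the shortest 2219 tested transcripts was -0.0946 in the deposited values, against -0.177 for the longest 2219, but over 5 other scalings it reached 0.0658, and under median scaling the shortest and the longest were at 0.0365 and 0.0465, so both its sign and the order by length depend on the scaling. Scaling over all features of the array stays open for the uneven counts, because the share that rose was 42.0%, 48.1% and 51.1% under 3 normalizations that set the tested transcripts alike between arrays, which by construction moves it toward an even split whatever the cause. The difference between the dimmest eighth and all tested transcripts, -0.359 in the deposited values, stayed below 0 under 4 of 5 other scalings, at -0.196 under median scaling, -0.173 and -0.160 under quantile normalization with normexp and without background correction, and -0.359 after centring, which cannot alter it, but was 0.0244 under quantile normalization over tested transcripts, which by construction makes signal distributions alike. Scaling as part of the cause and an effect of NO on weakly expressed transcripts, which was not tested, therefore cannot be told apart here. The detection rule also moves the counts. With a 2-fold minimum, 563 were higher and 1068 lower as reported. Detection on all 4 arrays left 526 and 744, and no filter gave 568 and 1272. Whether the rule adds to the falls of dim transcripts was not tested.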

How the results depend on the processing

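Centring, quantile normalization over tested transcripts, un-normalized quantile normalization without background correction, detection on all 4 arrays, single probe blocks, crossed pairing and the changes to list membership were chosen after seeing the data. Counts of higher and lower transcripts stayed within 1.5 times the reported 1680 and 3365 except for 2803 higher under normexp with median scaling, and 563 and 1068 with a 2-fold minimum, which by construction keeps fewer. The cause of the former was not tested. Of the 1680 and 3365, that median scaling kept 1623 and 2475. With 1 array left out, 1282 to 1327 were higher and 2327 to 2924 lower. An arm then holds 1 array, whose spread is assumed to be like that of the other group. Of 94 named transcripts that passed, 66 did so in all 18 alternatives, and another 11 in every alternative that tested them, since they were not detected on all 4 arrays. Among the 18, the series' value table holds the same values as the main fit and could not differ. Most of these transcripts were picked for large changes or small p in the same data, which favours passing. FVET_14061 reversed to 0.0147 under normexp with median scaling, and FVET_01393, at 0.00 in the deposited values, was at -0.0250 under normexp with quantile normalization, -0.0647 under normexp with median scaling, -0.0249 under quantile normalization without background correction, -0.00486 in the second probe block, and between -0.11 and 0.12 with 1 array left out. The causes were not tested. Camera called 8 lists higher, but 0 with an estimated correlation, and 3 when lists were compared with named transcripts alone. That background is smaller, and a smaller share of it fell. Median scaling made it 9, adding heat shock proteins and chaperones, and with 1 array left out it was 7 or 8, amino acid permeases being added without NO-exposed replicate 1. It called 0 lists lower, and 0 to 1 with 1 array left out, the 1 being sugar transporters without control replicate 2 or NO-exposed replicate 2. Averaging of probes in place of median polish was not run. Detection relative to random probes limits what can be said of dim transcripts: without the filter 1523 were higher and 3442 lower among 14163.

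The labels share replicate numbers across groups without saying that they pair cultures. With the replicate block 1576 transcripts were higher and 3170 lower, and 3 lists were higher, those of ribosome biogenesis and of cytosolic and mitochondrial ribosomal proteins. Camera calls ended for the tricarboxylic acid and glyoxylate cycles (adjusted p = 0.0520) and for heme synthesis and sulfur assimilation (0.0549 each). They also ended for tRNA synthetases (0.0642) and the respiratory chain (0.0951). Deviations of same-numbered arrays from their group means correlated at -0.289, and with crossed pairing as the block 2002 were higher and 4001 lower.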

Other observations

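All tests in this part were chosen after the results they bear on had been seen, except the comparison of ribosome biogenesis with lists of matched signal.

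Further groups of transcripts were defined by product name because their members had been seen to change, so their counts describe them and no test applies. Of 14 transcripts for synthesis of the branched-chain amino acids leucine, isoleucine and valine 12 rose and 0 fell. Ketol-acid reductoisomerase FVET_02845 rose 3.53-fold and 3-isopropylmalate dehydrogenase FVET_03345 3.34-fold. Of 6 transcripts for oxidising formaldehyde and formate 4 rose and 1 fell: glutathione-dependent formaldehyde-activating enzyme FVET_11461 rose 8.71-fold, esterase D (FVET_05441) 3.46-fold, formate dehydrogenase FVET_04767 3.18-fold and S-(hydroxymethyl)glutathione dehydrogenase FVET_02934 3.15-fold. Glutathione-independent formaldehyde dehydrogenase FVET_10422 fell, with a log2 change of -0.84. Glutathione-dependent formaldehyde dehydrogenase FVET_09321 differed by -0.58 and did not pass. Of 26 RNA helicases 16 rose and 1 fell, led by dbp-4 (FVET_06802), with a log2 change of 2.26. Of 18 transcripts for breaking down homogentisate and phenylacetate, intermediates of aromatic amino acid breakdown, 14 fell and 3 rose, among them fumarylacetoacetase FVET_04419 at -1.85 and homogentisate dioxygenase FVET_04418 at -1.39 on the log2 scale. In each of the 4 groups the larger count lay on the same side under 5 other scalings.

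Fumonisin synthesis, which could not be tested by locus, appears on the array as 49 features with FUM in their names. Of these 36 were detected on no array and 10 on at least 2 arrays. Among the latter 0 were higher and 5 lower after exposure. Of the 5, 4 carry the name of FUM21, a regulator of the fumonisin cluster. FUM21coding, I7fum21 and I8fum21 had log2 changes of -0.64, -1.02 and -0.87. I6fum21 was below background on both NO-exposed arrays and nominally 3.01-fold lower. The remaining feature, 1fum16, was also below background on both, with a mean RMA value of 7.08 there, and nominally 1.81-fold lower. FUM10coding counted as detected on all 4 arrays at means of 5.47 in controls and 5.28 after exposure, so the detection threshold does not order RMA values. FUM16coding, detected on all 4, differed by 0.014 (adjusted p = 0.953). Other scalings were not run for these features.

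Ribosome biogenesis transcripts rose by a median of 1.21 on the log2 scale. Their signal level as the cause is argued against: 100% of 10000 random lists of 23 transcripts matched on mean signal had a lower median, the highest being 0.53. Scaling is argued against as well, since the lowest list median over 5 other scalings was 1.13. That NO exposure raised them within 30 min is a hypothesis found and tested on the same data, with 2 cultures per group and a camera call that ended with an estimated correlation.

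Transcripts with large changes often carried consecutive FVET numbers. Of 248 transcripts changed at least 4-fold, 67 had a neighbour in number that changed at least 4-fold in the same direction, where 10000 reassignments among transcripts of like signal gave a mean of 4.91 and at most 22. The permutation p, one-sided, was 0.0001, the smallest they can give, which argues against chance placement among tested transcripts of like signal. They form 13 runs of higher and 17 of lower transcripts of up to 4 members. Examples are FVET_10789 beside P450 55A1 (FVET_10790), FVET_08692 beside FVET_08691, FVET_13848 beside flavohemoglobin FVET_13847, and FVET_04421 beside phenylacetate hydroxylase FVET_04422. If numbers follow the genome, neighbouring genes may have responded together, but whether they do is not stated in the sources used here, and overlapping gene models or shared probe sequence were not tested and stay open.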
